A study of Homo sapiens with 60 samples.

How the data were processed

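RNA was taken from HT29 cells after 24 h with an extract or with vehicle. Libraries were made with an MGIEasy directional kit and sequenced on an MGIseq instrument as paired reads of 100 bp from RNA with an integrity number above 7, per the labels' protocols. The sample characteristics give the vehicle as 0.1% DMSO and the series' design text as 2% DMSO, a difference that was not settled here. The design text also speaks of ethanol extracts, a wortmannin control and excluded outliers, which were not analysed here. The deposited expected counts come from RSEM 1.3.3, with FastQC 0.11.9, Trim Galore 0.6.5 and STAR 2.7.3a also named, on GRCh38 (hg38), per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Such expected counts divide a read that matches several genes between them, so values of near-identical relatives depend on that division. The deposited table held 60675 gene identifiers and 60 libraries, its values were not scaled between libraries, and 27.7% of its values above 0 were not whole numbers. They were rounded to whole numbers before any test.

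Each column was matched to its sample by the sample description, and groups and replicate numbers came from the sample titles and characteristics. The libraries of 19 groups of 3 (vehicle and 6 extracts at 3 doses) entered the fit, 57 in all, with 38 residual degrees of freedom. The 3 Soshiho-tang libraries, 1 per dose, entered no test. Symbols were found for 41209 identifiers (14975 of those tested) in a table of gene names, and coordinates and gene types for 57055 (16929 of those tested, 13068 protein coding) in GENCODE release 29, which may not be the release the submitters used. No column was left unused.

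The tests ran in R 4.3.3. Genes were kept by edgeR 4.0.16's filterByExpr, which left 17049 genes holding 99.95% of all counts, and libraries were scaled by TMM. All 29 comparisons of genes (18 with vehicle, 6 of high against low dose and 5 between extracts) used edgeR's quasi-likelihood test with robust estimation in 1 fit over all 57 libraries, with no blocking term. Adjusted p-values are Benjamini-Hochberg values over the 17049 genes of a comparison, with a threshold of 0.05. Fold changes are log2 values of edgeR's fit at its default prior count. Their standard errors come from the fold change and its test statistic. A prior count of 2 was used for log2 CPM values, which served the principal component, the covariances, the pairing check and the Soshiho-tang ratios. Values in CPM use TMM-scaled library sizes. In 12 comparisons (high dose against vehicle and against low dose) 38 lists of genes, written out from general knowledge of pathways and cell types, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, where at least 5 members were measured. The lists held 750 genes, of which 650 were tested, and 5 of the lists were markers of other cell types. Their adjusted p-values are over the lists of a comparison. "Adjusted over the list alone" means a Benjamini-Hochberg adjustment over the measured members of that list.

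The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, among protein-coding genes past the threshold with at least 5 CPM in the higher group and the values of the groups all apart (chance alone parts 3 against 3 so in 10% of genes), the 8 largest changes each way against vehicle at the high dose and the 5 largest each way in the other comparisons, the 4 list members with the smallest p per list, and 10 fixed readouts. Some genes that the rule took are not reported here. For Soshiho-tang it took the 5 largest and 5 smallest ratios of the high-dose library to the vehicle mean, outside the vehicle range, in 1 direction at the high and medium dose. The alternatives were DESeq2's size factors, no filter on low counts (at least 1 count in all), DESeq2 1.42.0's own test, a fit on the groups compared alone, a replicate block, an estimated correlation in the list test, and leaving out each library in turn. After the data had been seen, 2 more were added: a term for the part of the library numbering (earlier or later), and a fit on the earlier-numbered libraries alone. The order term is estimated only from Saengmaek-san and Guibi-tang, whose libraries fell in both parts.

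Same-numbered libraries were checked for pairing through the correlation of their deviations from the group means. Of the comparisons, only Saengmaek-san against Guibi-tang at the high dose had all 3 correlations above 0.1 (0.144, 0.129 and 0.286). There the replicate block gave 75 genes and the fit without it 63. In both groups replicates 1 and 2 are earlier-numbered and replicate 3 is later-numbered, so the library order alone could give such correlations. Saengmaek-san at the high against the low dose, parted alike, had 0.179, 0.041 and 0.282. The check therefore cannot tell pairing from library order. The covariance of fold changes that share the vehicle was set against 100 simulated sets of unchanged groups. For Soshiho-tang, list medians were placed among 10000 random lists of the same size matched on mean expression, as a description of those libraries.

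The tests were run first on simulated counts with 50 genes changed at each of 4 fold sizes. The simulated spread was that of the fit with the order term. It is smaller than that of the main fit without the term (common coefficient of variation 0.0434 against 0.0524). The shares found may therefore be too high for the main fit. For Menthae Herba at the high dose against vehicle 48%, 64%, 82% and 88% of genes changed by 1.25, 1.5, 2 and 3 times were found, with 6 unchanged genes called. For Soyo-san at the high dose, with a simulated difference between library parts added, 1071 unchanged genes were called without the order term and 3 with it, and 36%, 64%, 78% and 84% of the changed genes were found with it. The difference added was the estimate of the order term itself, the same in every later library. The term was therefore bound to remove it, and this does not test an offset particular to 1 set of libraries. In a simulation on Menthae Herba with 38 lists the changed list was called and 0 of the unchanged ones. Total counts of 19.5 to 41.9 (in units of 1e6) per library set the precision of low genes, and intervals cover counting and replicate spread only.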

Results

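HT29, an established human colorectal adenocarcinoma line of epithelial origin, was exposed for 24 h to hot-water extracts of medicinal herbs, and its transcripts were counted by RNA sequencing. The extracts came from 2 single herbs, Menthae Herba (mint) and Saposhnikoviae Radix, and from 5 multi-herb formulas, Saengmaek-san, Guibi-tang, Soyo-san, Okbyeongpung-san and Soshiho-tang. Each was given at a high (500 µg/mL), medium (100 µg/mL) and low (20 µg/mL) dose. Soshiho-tang had 1 library per dose, each of the other 6 extracts 3, and 3 libraries came from cells given DMSO (vehicle). Whether cells given an extract also received DMSO is not in the sample labels used here. Total counts, in units of 1e6, ran from 19.5 to 41.9 per library with a median of 29.2, and 17049 genes entered the tests. Mitochondrially encoded genes took 9.74% to 13.9% of the counts of a library and its 10 highest genes 9.88% to 13.3%. The mitochondrial share was 12.8%, 12.8% and 13.5% in the vehicle libraries, above all but 2 of the treated ones, a difference that enters every comparison with vehicle and whose cause was not tested. Nothing in the labels says whether replicates came from separate cultures, so p-values of single genes measure the spread between these libraries, which may be technical. Those of the list test set the genes of a list against all other genes. With the preset correlation they do not measure the spread between libraries, and very small values are not evidence from replicates. The 57 replicate pairs all differed by more than counting noise, with 1.85 to 24.3 times the chi-square expected of one library counted again.

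The libraries parted along the numbering of the library names. The 31 earlier-numbered libraries lay between -19.0 and -8.22 on the first principal component (12.8% of variance) and the 29 later-numbered ones between 2.86 and 22.5. The parts were cut by the sign of this component, which changed at 1 point of the numbering. The gap and the genes below therefore describe the cut and are no independent test of it. Between these parts, 2719 genes were higher and 2334 lower in the later libraries once treatment was allowed for, of which 82 differed by 1 or more on the log2 scale. The median total count, in units of 1e6, was 34.7 in the earlier libraries and 24.9 in the later ones. MYC, a growth-driving transcription factor, was 0.23 ± 0.03 (log2 ± SE) higher in the later libraries, the proliferation marker MKI67 0.19 ± 0.05 and the chemokine CXCL1 0.29 ± 0.07 higher, and the cell-cycle inhibitor CDKN1A fell by 0.24 ± 0.06. Chosen after their values were seen, the ribosomal protein gene RPL11 and the RNA-binding protein gene YBX1 were 0.38 ± 0.03 and 0.37 ± 0.03 higher. All vehicle, Menthae Herba and Saposhnikoviae Radix libraries were in the earlier part and all Soyo-san and Okbyeongpung-san libraries in the later part, while Saengmaek-san and Guibi-tang had libraries in both. A fit with the part as an added term (the order term), chosen after this was seen, takes its estimate from those 2 formulas alone. Its counts of genes stand beside each comparison with vehicle, while some single genes and lists are given without it. Where all libraries compared lie in 1 part, as for Menthae Herba and Saposhnikoviae Radix against vehicle, the term hardly shifts a fold change. There it acts on the estimated spread, whose common coefficient of variation was 0.0524 without and 0.0434 with it.

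**Figure D1:**
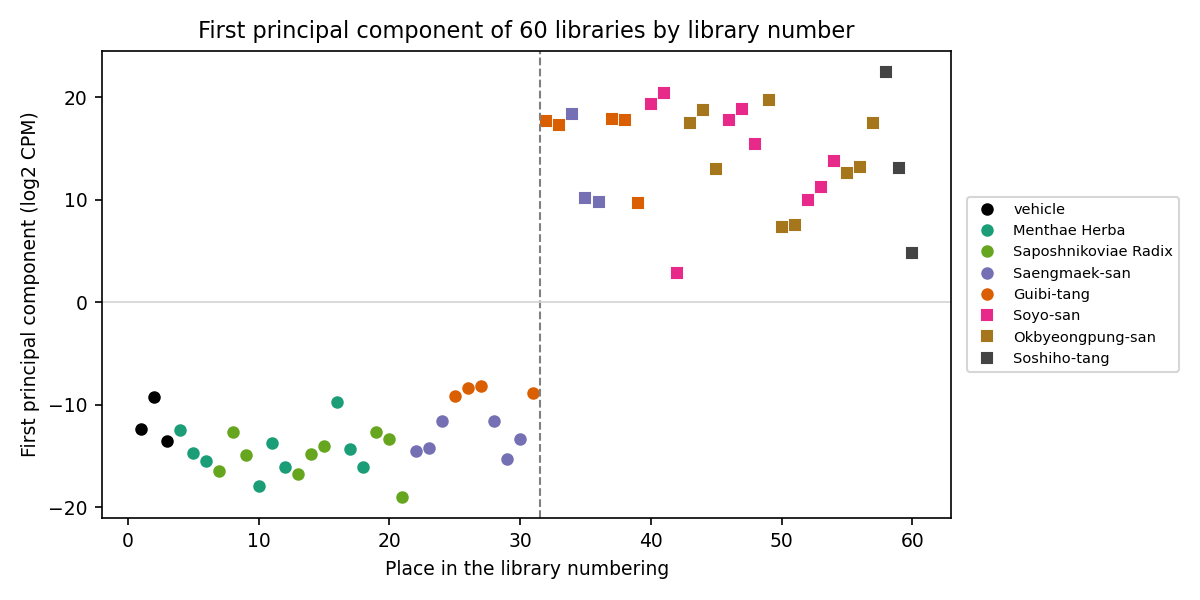
First principal component of log2 CPM (vertical axis) against the place in the library numbering (horizontal axis), 1 point per library, coloured by extract, with a dashed line between the earlier (circles) and later (squares) parts. The 31 earlier libraries all lie below -8.22 and the 29 later ones all above 2.86, whichever extract they received. The parts were cut by the sign of this component.

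Menthae Herba at the high dose was compared with vehicle to find what the mint extract does to these cells. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), rose from 0.488 ± 0.132 to 6.13 ± 0.517 CPM (counts per 1e6 counts, mean ± SD, n = 3), a log2 change of 3.62 ± 0.26 (SE). Genes of the NRF2 oxidant defence rose with it: the cystine importer SLC7A11 by 1.11 ± 0.13, HMOX1 (haem oxygenase) by 0.97 ± 0.10, from 10.4 ± 0.602 to 20.4 ± 0.504 CPM, and GCLM, of glutathione synthesis, by 0.97 ± 0.07. CYP1B1 rose by 0.93 ± 0.07, the aldehyde dehydrogenase ALDH3A1 by 0.89, and the aldo-keto reductases AKR1C3 and AKR1B10 by 0.88 and 0.87. The largest falls by the naming rule were those of DHRS2 (-1.18 ± 0.11), the surface glycoprotein CD200 (-0.95), the superoxide-producing oxidase NOX1 (-0.82 ± 0.08), SPEG (-0.81), the metallothioneins MT2A (-0.80) and MT1E (-0.78), the secreted mucin MUC2 (-0.76 ± 0.15, from 29.3 ± 1.04 to 17.4 ± 0.352 CPM) and the proton pump subunit ATP6V1B1 (-0.75). In all, 782 genes rose and 679 fell (edgeR, adjusted p under 0.05), 16 and 31 of them by 1 or more on the log2 scale. With the order term 1090 rose and 886 fell. That fit shared 1460 of the 1461 calls, which is no check on the library order, since both groups lie in the earlier part. In the earlier-numbered libraries alone 2570 genes passed. The high dose count was 825 and 750 without high replicates 1 and 2, and 783, 916 and 963 without vehicle replicates 1, 2 and 3.

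By gene list, 6 of 8 measured AhR targets rose under the high dose of Menthae Herba (8 adjusted over the list alone; limma's camera, adjusted p = 2.9e-37), as did 23 of 26 NRF2 targets (24 adjusted over the list alone; adjusted p = 8.2e-62). Of 29 glycolysis and hypoxia genes 12 rose (19 rose and 1 fell adjusted over the list alone; adjusted p = 2.2e-11), among them HK2 (0.30) and the glucose importer SLC2A1 (0.30). Of 30 genes of G1/S and DNA replication 12 rose (18; adjusted p = 7.2e-12), including RRM2 (0.29) and CDC6 (0.27). Cholesterol synthesis had 7 of 24 genes up and 1 down (12 and 1 adjusted over the list alone; adjusted p = 2.2e-06) and fatty acid synthesis 3 of 13 up (4; adjusted p = 2.1e-04). The ATF4 amino acid response had 6 of 25 up (6; adjusted p = 1.3e-04; TRIB3 0.29, PSAT1 0.29) and iron handling 5 of 10 up and 1 down (6 and 1; adjusted p = 3.4e-05; TFRC 0.32). Of 16 xenobiotic metabolism genes 6 rose (6 up and 2 down adjusted over the list alone; adjusted p = 6.7e-04), among them the exporter ABCC2 (0.73) and UGT1A1 (0.49), with a list median of -0.03, a mean of 0.01 and a test in the upward direction. Of 18 goblet and secretory genes 7 fell (10 adjusted over the list alone; adjusted p = 1.9e-06), including the secretory lineage factor ATOH1 (-0.55) and REG4 (-0.39). So did 5 of 17 WNT targets (7 fell and 1 rose adjusted over the list alone; adjusted p = 5.9e-04; NOTUM -0.61, EPHB3 -0.29). Lower too were 5 of 8 metallothionein and metal response genes, of which 1 rose (5 and 1; adjusted p = 6.7e-04; MT1G -1.75, MT1X -1.15; the zinc importer SLC39A10 0.45). These calls held with an estimated correlation between genes. A further 6 lists passed with the preset correlation only: the adjusted p with an estimated correlation was 0.0508 for the unfolded protein response, 0.0633 for the proteasome, 0.108 for MYC and ribosome biogenesis, 0.414 for oxidative phosphorylation, 0.465 for mitochondrially encoded genes and 0.414 for the interferon response.

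**Figure D2:**
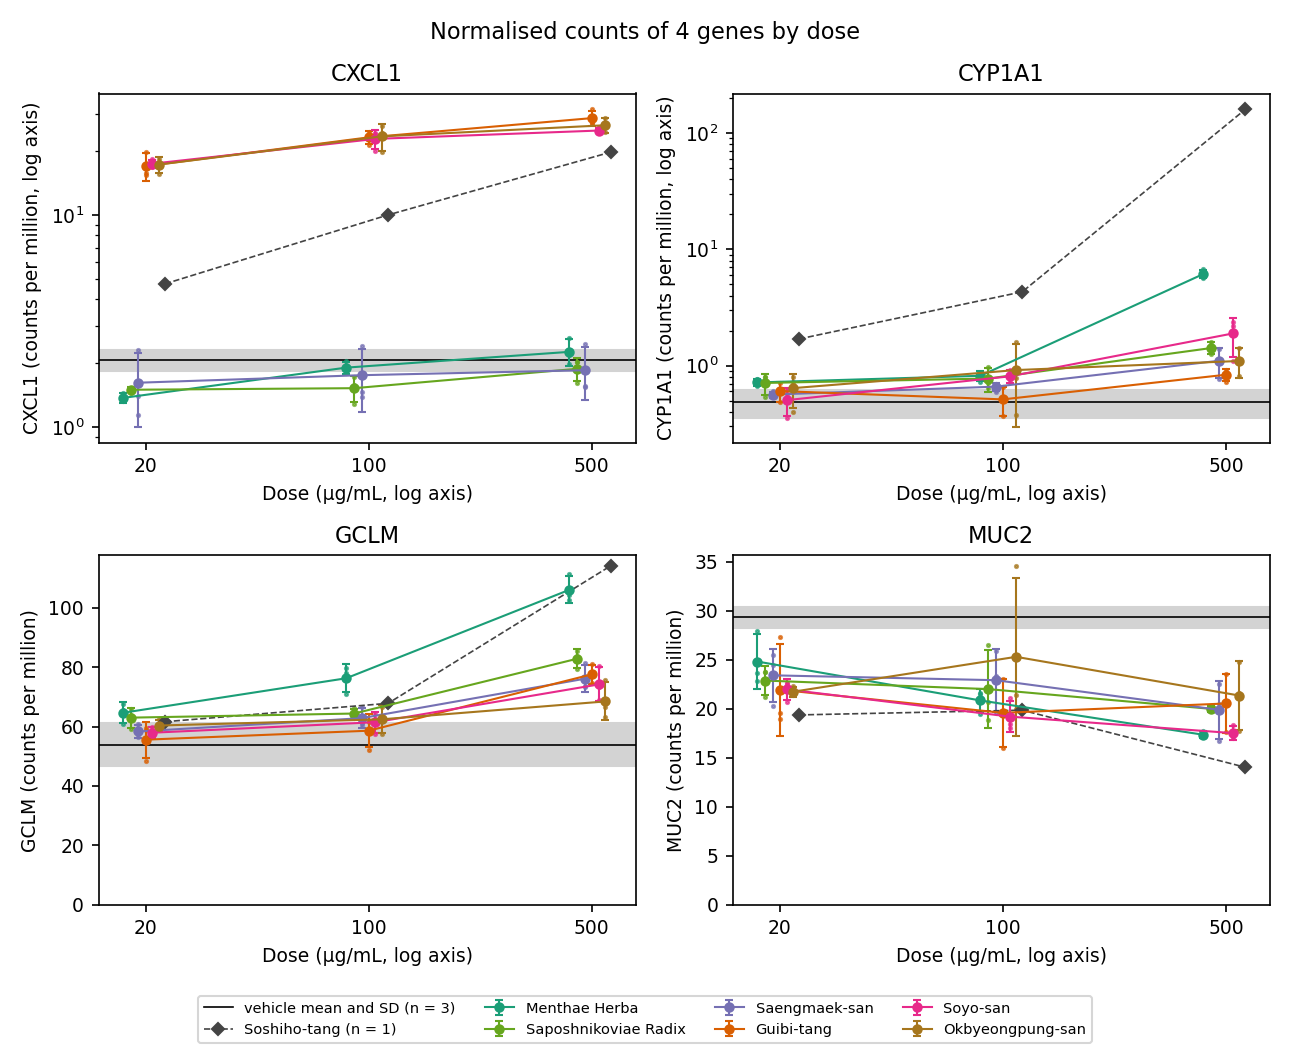
CPM (vertical axis, logarithmic for CXCL1 and CYP1A1) by dose in µg/mL (logarithmic axis); large points with bars are means ± SD of 3 libraries, small points single libraries, the line with its grey band the vehicle mean ± SD, and diamonds the 1 Soshiho-tang library per dose. CXCL1 averaged 28.6, 25.0 and 26.5 CPM under the high doses of Guibi-tang, Soyo-san and Okbyeongpung-san against 2.07 CPM in vehicle, and CYP1A1 averaged 6.13 CPM under the high dose of Menthae Herba.

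The lower doses of Menthae Herba asked whether these changes scale with dose. At the medium dose GCLM averaged 76.3 ± 4.64 CPM and MUC2 20.9 ± 1.20 CPM, 57 genes rose and 69 fell against vehicle, and 6 of 26 NRF2 targets rose (13 adjusted over the list alone). At the low dose 2 genes rose and 8 fell, and CYP1A1 averaged 0.716 ± 0.0502 CPM. Set directly against the low dose, the high dose had higher CYP1A1 (3.09 ± 0.24), CYP1B1 (1.00), HMOX1 (0.94), ALDH3A1 (0.92) and SLC7A11 (0.78). It had lower DHRS2 (-1.04), CD200 (-0.96), NOX1 (-0.87), RNF144B (-0.80) and MT1E (-0.77), with 192 genes higher and 210 lower (edgeR, n = 3 and 3). NRF2 targets had 21 of 26 genes higher at the high dose (25 adjusted over the list alone), AhR targets 6 of 8 (7), and metallothioneins 4 of 8 lower and 1 higher (5 and 1). Of 19 lists past camera's test in this contrast, 4 lost it with an estimated correlation, with adjusted p of 0.398 for the heat shock response, 0.0699 for MYC and ribosome biogenesis, 0.0636 for the interferon response (lower) and 0.175 for the proteasome. With the order term 151 rose and 149 fell at the medium dose, 48 and 76 at the low dose, and in the earlier-numbered libraries alone 849, 546 and, high against low, 803 genes passed. The medium dose count was 19, 66 and 41 without medium replicates 1, 2 and 3, and 30, 68 and 57 without vehicle replicates 1, 2 and 3. The low dose count was 3 and 3 without low replicates 1 and 2, and 4, 4 and 3 without vehicle replicates 1, 2 and 3. Against the low dose the count was 266 and 251 without high replicates 2 and 3, and 266 and 266 without low replicates 2 and 3.

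Saposhnikoviae Radix at the high dose raised genes of oxidant defence against vehicle. SLC7A11 rose by 0.63 ± 0.13 (log2 ± SE, n = 3 and 3), GCLM by 0.62 ± 0.07, from 54.0 ± 7.22 to 82.9 ± 3.26 CPM, the steroid-reducing AKR1C2 and AKR1C3 by 0.59 and 0.56, CYP1B1 by 0.57 ± 0.07, CLIP4 by 0.45, AKR1B10 by 0.42 and the splicing-factor kinase CLK1 by 0.42. CYP1A1, at 1.42 ± 0.170 CPM, rose by 1.52 ± 0.29 (edgeR, adjusted p = 0.00335). SLC6A20 (-0.48), PIGZ (-0.41), the G-protein regulator RGS2 (-0.39), NFKBIZ (-0.37), the growth factor BMP2 (-0.37), U2AF1L4 (-0.36), ATP6V1B1 (-0.35) and AHDC1 (-0.33) fell, and MUC2 had a log2 change of -0.55 that did not pass (adjusted p = 0.0832). In all 50 genes rose and 35 fell. With the order term, again with both groups in the earlier part, 110 rose and 90 fell. The high dose count was 17 and 22 without high replicates 1 and 2, and 24, 45 and 47 without vehicle replicates 1, 2 and 3.

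Among lists, 5 of 8 AhR targets (6 adjusted over the list alone; camera adjusted p = 8.2e-17) and 11 of 26 NRF2 targets (14; adjusted p = 3.3e-26) rose under Saposhnikoviae Radix. No goblet and secretory gene of 18 and no G1/S gene of 30 passed over all genes (3 goblet genes fell and 4 G1/S genes rose adjusted over the list alone). Camera still called the first list lower (median -0.16; adjusted p = 4.1e-05) and the second higher (median 0.08; adjusted p = 1.0e-07). With an estimated correlation the adjusted p of the goblet list was 0.00351 and that of G1/S 0.0492, which became 0.0644 with the order term. A further 7 lists passed with the preset correlation and not with an estimated one, whose adjusted p was 0.134 for the unfolded protein response, xenobiotic metabolism, the immediate early genes and the mitochondrially encoded genes, 0.202 for glycolysis, 0.682 for MYC and ribosome biogenesis and 0.78 for oxidative phosphorylation. Xenobiotic metabolism had a median of -0.01, a mean of 0.02 and an upward test. At the medium dose 2 genes rose and 3 fell, and at the low dose 11 rose and 18 fell. Their counts with the order term were 14 and 25, then 46 and 69. Between high and low dose AKR1C2 (0.55), CYP1B1 (0.50), the retinaldehyde dehydrogenase ALDH1A3 (0.40), GCLM (0.39) and ADGRF1 (0.32) were higher at the high dose and no gene was lower. AhR targets (1 of 8 higher, 6 adjusted over the list alone), NRF2 targets (2 of 26; 14) and the unfolded protein response (0 of 20; 0; adjusted p = 0.018 with an estimated correlation) held as lists between the doses. The medium dose count was 3 without medium replicate 3, and 3 and 8 without vehicle replicates 1 and 2. The low dose count was 8 and 5 without low replicates 1 and 3, and 5, 6 and 6 without vehicle replicates 1, 2 and 3. Against the low dose the count was 1 and 3 without high replicates 1 and 2, and 3, 3 and 1 without low replicates 1, 2 and 3.

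Saengmaek-san at the high dose gave CLK1 its largest rise by the naming rule, 0.64 ± 0.06 (log2 ± SE), from a vehicle mean of 32.1 to 50.1 CPM (n = 3 and 3). SLC7A11 (0.58), GCLM (0.50 ± 0.08), AKR1C3 (0.49), the adaptor DAPP1 (0.48), CLIP4 (0.48), AKR1C1 (0.47) and AKR1B10 (0.45) rose, and CYP1A1 rose by 1.11 ± 0.31 to 1.10 ± 0.315 CPM (edgeR, adjusted p = 0.0275). PRR36 (-0.72), the homeobox gene HOXB2 (-0.67), MUC2 (-0.56; adjusted p = 0.0289), the kinase WNK4 (-0.52), the selenoprotein SELENOW (-0.51), the membrane mucin MUC12 (-0.48), the recombination gene RAD52 (-0.48) and the MAPK phosphatase DUSP8 (-0.47) fell. In all 407 genes rose and 323 fell, and with the order term 626 rose and 463 fell, sharing 679 of the 730 calls. The balance of rises and falls was not stable: DESeq2's size factors gave 320 up and 345 down, and no filter on low counts 272 and 488. A fit of these 2 groups alone called 51 genes, 9 up and 42 down. In the earlier-numbered libraries alone, 2 of the 3 treated ones, 1537 genes passed. The high dose count was 125 and 459 without high replicates 2 and 3, and 95 and 365 without vehicle replicates 1 and 3.

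NRF2 targets (11 of 26 up, 14 adjusted over the list alone; camera adjusted p = 2.4e-17), G1/S and DNA replication (8 of 30 up, 19; adjusted p = 2.1e-12; CDC45 0.22, PCNA 0.15) and WNT targets (2 of 17 down, 6; adjusted p = 7.4e-05), among them SOX9 (-0.27) and EPHB3 (-0.27), moved as lists under Saengmaek-san and held with an estimated correlation. Another 11 lists did not hold. Among them 4 of 8 AhR targets rose (adjusted p = 0.122 with an estimated correlation), 3 of 25 immediate early genes fell (0.0874 as that p; EGR1 -0.42, DUSP1 -0.36, FOS -0.29) and 2 of 18 goblet genes fell (0.0874 likewise). At the medium dose 28 genes rose and 43 fell, and at the low dose 6 rose and 10 fell. Their counts with the order term were 161 and 136, then 19 and 27. From low to high dose 2 genes were higher, AKR1C1 (0.40) and GCLM (0.38; each adjusted p = 0.0355), and 2 outside the naming rule were lower. NRF2 targets (2 of 26 higher, 16 adjusted over the list alone) held as a list (adjusted p = 8.4e-04 with an estimated correlation). The medium dose count was 4 without medium replicate 2, and 5, 34 and 19 without vehicle replicates 1, 2 and 3. The low dose count was 9, 6 and 7 without low replicates 1, 2 and 3, and 6 and 5 without vehicle replicates 1 and 3. No gene passed between high and low dose when any one of the 6 libraries was left out, against 22 with DESeq2.

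Guibi-tang at the high dose raised neutrophil-attracting chemokines. CXCL1 rose from 2.07 ± 0.234 to 28.6 ± 2.47 CPM (n = 3 and 3), a log2 change of 3.78 ± 0.14, and CXCL8 from 7.87 ± 0.194 to 27.9 ± 2.64 CPM, a change of 1.83 ± 0.09. The secreted protease inhibitor PI3 (elafin) rose by 2.45 ± 0.09, the leukocyte adhesion molecule ICAM1 by 1.43 ± 0.11, the apoptosis inhibitor BIRC3 by 1.26, AKR1C2 by 0.77, the iron-scavenging LCN2 by 0.70 and the RNase ZC3H12A by 0.68. PRR36 (-0.57), SELENOW (-0.49), MAST3 (-0.48), the immediate early factor EGR1 (-0.48), WNK4 (-0.48), SPEG (-0.46) and the endothelin EDN1 (-0.42) fell. HMOX1 rose by 0.47 (edgeR, adjusted p = 0.00401) and TXNIP fell by 0.23 (adjusted p = 0.0412), whereas MUC2 (-0.53; adjusted p = 0.051) and CYP1A1 (0.76; adjusted p = 0.214) did not pass. Altogether 219 genes rose and 166 fell, 28 and 2 by 1 or more on the log2 scale, and with the order term 362 rose and 255 fell, sharing 370 of the 385 calls. In the earlier-numbered libraries, 2 of the 3 treated ones, 714 passed. The high dose count was 199, 255 and 211 without high replicates 1, 2 and 3, and 158, 232 and 188 without vehicle replicates 1, 2 and 3.

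Of 19 measured NF-kB and inflammatory cytokine genes 16 rose under Guibi-tang (18 adjusted over the list alone; median 1.34; camera adjusted p = 5.5e-129), including CXCL3 (2.56), CXCL2 (1.89), IL32 (1.34) and the feedback inhibitor TNFAIP3 (0.79); CCL20 went from 0.143 ± 0.0516 to 3.73 ± 0.823 CPM. Of 29 interferon response genes 9 rose (23 adjusted over the list alone; adjusted p = 1.1e-18), as did 17 of 26 NRF2 targets (25 up and 1 down; adjusted p = 4.8e-36). G1/S genes (4 of 30 up, 14 adjusted over the list alone), goblet genes (2 of 18 down, 6), WNT targets (2 of 17 down, 3), AhR targets (3 of 8 up, 5) and lysosome genes (1 of 27 up, the autophagy receptor SQSTM1 at 0.53) also held with an estimated correlation. The AhR list held at an adjusted p of 0.0443, which became 0.0542 with the order term. The other 9 called lists did not hold, among them cholesterol synthesis (adjusted p = 0.0602 with an estimated correlation), antigen presentation (0.0942 likewise) and xenobiotic metabolism (0.136 likewise). At the medium and low doses CXCL1 averaged 23.2 ± 1.64 and 17.0 ± 2.51 CPM, and 14 and 12 of the 19 NF-kB genes rose (17 and 16 adjusted over the list alone). The medium dose had 98 genes up and 85 down and the low dose 86 and 59. The fit with the order term called 83 and 55, then 116 and 90, sharing 88 of the 183 and 90 of the 145 calls. The medium dose count was 604, 85 and 121 without medium replicates 1, 2 and 3, and 72, 116 and 71 without vehicle replicates 1, 2 and 3. The low dose count was 576, 58 and 61 without low replicates 1, 2 and 3, and 64, 76 and 66 without vehicle replicates 1, 2 and 3. Replicate 1 is the only earlier-numbered library at the medium and at the low dose. Without it only later libraries are set against the earlier vehicle, so the counts of 604 and 576 are confounded with the library order.

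High against low dose, Guibi-tang had higher CXCL1 (0.75 ± 0.11), the aldo-keto reductases AKR1B10 (0.63) and AKR1C2 (0.61), BIRC3 (0.54), PI3 (0.54) and CXCL8 (0.54). It had lower SELENOW (-0.41), TPPP3 (-0.34), ANXA13 (-0.34) and the sterol reductase TM7SF2 (-0.30), with 36 genes higher and 24 lower. At the high dose 8 of 19 NF-kB genes (9 adjusted over the list alone; camera adjusted p = 4.3e-20) and 10 of 26 NRF2 targets (18; adjusted p = 3.8e-37) were higher. Goblet genes were lower as a list with no single gene past the test over all genes (1 adjusted over the list alone; adjusted p = 0.0279 with an estimated correlation, and 0.0692 with the order term besides). Against the low dose the count was 27 and 23 without high replicates 1 and 2, and 22 and 24 without low replicates 2 and 3.

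Soyo-san, a formula that contains mint, raised CXCL1 and CXCL8 as well at the high dose. CXCL1 reached 25.0 ± 0.761 CPM (log2 3.59 ± 0.14 against vehicle, 3.30 with the order term), PI3 rose by 2.35 (2.27), CXCL8 by 1.69 (1.55), ICAM1 by 1.29 (1.11), BIRC3 by 1.07 (0.93), the interferon-induced GTPase MX1 by 0.91 (1.04) and CLIP4 by 0.76 (0.97). The chloride channel gene BEST1 rose by 0.84 without the order term, and with it the change was 0.25 and did not pass (adjusted p = 0.509). Falls that held with the term were those of PRR36 (-1.08; -0.95 with it), the urea transporter SLC14A1 (-1.06; -1.08), EGR1 (-0.89; -0.94), CD200 (-0.86; -1.09), MUC2 (-0.74; -0.65), SELENOW (-0.68; -0.54) and SELENON (-0.61; -0.54), while that of MOGAT3 (-0.63) became -0.45 (adjusted p = 0.0704). CYP1A1 rose by 1.94 ± 0.29 to 1.89 ± 0.697 CPM (1.72 with the term). Without the term 1369 genes rose and 1097 fell, and with it 668 and 553, the fits sharing 725 calls (edgeR, n = 3 and 3). The high dose count was 1037 and 1271 without high replicates 1 and 2, and 1406 and 1554 without vehicle replicates 1 and 3.

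Under Soyo-san 16 of 19 NF-kB genes (17 adjusted over the list alone; camera adjusted p = 6.1e-64), 19 of 29 interferon response genes (21; adjusted p = 7.3e-12) and 6 of 8 AhR targets (7; adjusted p = 9.9e-08) rose. So did 18 of 26 NRF2 targets with 1 down (22 and 1; adjusted p = 1.0e-17) and 15 of 30 G1/S genes (20; adjusted p = 7.3e-12). Falls were seen in 5 of 17 WNT targets (6; adjusted p = 0.00114) and 4 of 18 goblet genes (7; adjusted p = 0.00163). All 7 lists held with an estimated correlation. Given the order term, 14 NF-kB, 12 interferon, 13 NRF2 and 12 G1/S genes rose. Among 26 MYC and ribosome biogenesis genes 14, and among 26 proteasome genes 12, rose without the term, at adjusted p of 0.0508 and 0.103 with an estimated correlation, and with the term 5 MYC-list genes rose and 1 fell. Of 25 immediate early genes 5 fell (adjusted p = 0.0614 with an estimated correlation), and 8 with the order term (0.00722 as that p). MYC itself changed by -0.13 (adjusted p = 0.239) and, with the order term, fell by 0.37 (6.9e-06). Heat shock genes as a list had a camera adjusted p of 0.864 without the term, and with it 7 of 16 fell and 1 rose (adjusted p = 2.1e-07, or 0.11 with an estimated correlation). Changes seen only with the term assume that the order difference of Saengmaek-san and Guibi-tang also holds for the Soyo-san libraries. For MYC that difference was 0.23. No later-numbered vehicle library was used here to check this.

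At the medium and low doses of Soyo-san CXCL1 averaged 22.8 ± 2.35 and 17.4 ± 0.756 CPM, and 16 and 13 of 19 NF-kB genes rose (17 and 16 adjusted over the list alone). The medium dose had 950 genes up and 732 down against vehicle and the low dose 348 and 322. Their counts with the order term were 267 and 239, then 332 and 333, with 277 and 224 calls shared. High against low dose, in which every library is of the later part, CYP1A1 was higher by 1.89 (edgeR, adjusted p = 0.00141), CXCL1 by 0.52, AKR1C2 by 0.52, AKR1B10 by 0.47, GPAT3 by 0.43 and CXCL8 by 0.41. ZNF704 (-0.38), TPPP3 (-0.34), the antiproliferative BTG2 (-0.32), SLC22A23 (-0.27) and CLEC3A (-0.22) were lower, with 15 genes higher and 7 lower. In this contrast 2 of 8 AhR targets (6 adjusted over the list alone), 5 of 26 NRF2 targets (19) and 2 of 19 NF-kB genes (7) were higher at the high dose, and these lists and those of the unfolded protein response, G1/S, MYC and ribosome biogenesis (higher) and WNT targets (lower) held with an estimated correlation. The medium dose count was 898 and 653 without medium replicates 1 and 2, and 806 and 827 without vehicle replicates 1 and 3. The low dose count was 415, 182 and 385 without low replicates 1, 2 and 3, and 314, 353 and 261 without vehicle replicates 1, 2 and 3. Against the low dose the count was 0, 0 and 80 without high replicates 1, 2 and 3, and 12, 9 and 4 without low replicates 1, 2 and 3.

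Okbyeongpung-san, a formula that contains Saposhnikoviae Radix, gave CXCL1 a mean of 26.5 ± 2.11 CPM at the high dose (log2 3.67 ± 0.14 against vehicle, 3.38 with the order term). PI3 rose by 2.47 (2.39 with the term), CXCL8 by 1.68 (1.54), ICAM1 by 1.3 (1.12), BIRC3 by 1.10 (0.96), MX1 by 1.02 (1.15) and LCN2 by 0.74 (0.51). The interferon-induced IFI6 rose by 0.78, and its 0.72 with the term did not pass (adjusted p = 0.0641). EGR1 (-0.84; -0.89 with the term), PRR36 (-0.74; -0.61), SLC14A1 (-0.67; -0.69), PIGZ (-0.57; -0.48) and DUSP8 (-0.54; -0.41) fell. NPIPB12 (-0.72 ± 0.18), MUC12 (-0.55 ± 0.15) and the serotonin receptor HTR1D (-0.52 ± 0.13) fell without the term. With it their changes were -0.47 ± 0.20, -0.22 ± 0.15 and -0.31 ± 0.14 and did not pass (adjusted p = 0.248, 0.521 and 0.284). CYP1A1 rose by 1.15 (adjusted p = 0.0201), and its 0.93 with the term did not pass (adjusted p = 0.19). In all 744 genes rose and 517 fell, and with the term 222 and 179, the fits sharing 227 calls (edgeR, n = 3 and 3). The high dose count was 610, 642 and 801 without high replicates 1, 2 and 3, and 431 and 601 without vehicle replicates 1 and 3.

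NF-kB genes (17 of 19 up, 17 adjusted over the list alone; camera adjusted p = 1.7e-91), interferon response genes (17 of 29 up, 24; adjusted p = 2.5e-16) and G1/S genes (7 of 30 up, 13; adjusted p = 3.0e-08) moved as lists under Okbyeongpung-san and held with an estimated correlation. The same held for immediate early genes (6 of 25 down, 8; adjusted p = 7.4e-06) and goblet genes (3 of 18 down, 7; adjusted p = 0.00121). Given the order term, 15 NF-kB, 11 interferon and 3 G1/S genes rose and 7 immediate early genes fell. Of 26 NRF2 targets 8 rose (13 up and 1 down adjusted over the list alone; adjusted p = 0.0903 with an estimated correlation) and 4 of 8 AhR targets (0.124 as that p), of which none rose with the term. Heat shock genes had a camera list p of 0.562 without the term, and with it 7 of 16 fell (1.2e-13, and 0.0188 with an estimated correlation). That fall appears only if the order difference of Saengmaek-san and Guibi-tang also holds for the Okbyeongpung-san libraries, which was not tested. The medium dose had 370 genes up and 269 down and the low dose 808 and 690. With the term these were 169 and 165, then 441 and 401, with 134 and 407 calls shared. At these doses CXCL1 averaged 23.5 ± 3.39 and 17.3 ± 1.46 CPM, and 15 and 14 of 19 NF-kB genes rose (16 and 16 adjusted over the list alone). High against low, CXCL1 alone passed in edgeR (0.61 ± 0.11; adjusted p = 0.0202), with 807 genes at an unadjusted p under 0.05 and 2 genes by DESeq2. NF-kB genes (1 of 19 higher, 10 adjusted over the list alone) held as a list and so did cholesterol synthesis (lower, 0 of 24; 2 lower adjusted over the list alone; adjusted p = 0.0408 with an estimated correlation). The medium dose count was 159 and 393 without medium replicates 1 and 3, and 261, 384 and 207 without vehicle replicates 1, 2 and 3. The low dose count was 866 and 648 without low replicates 1 and 3, and 760 and 821 without vehicle replicates 1 and 3. No gene passed between high and low dose without high replicate 1 or 2 or any one of the low replicates.

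**Figure D3:**
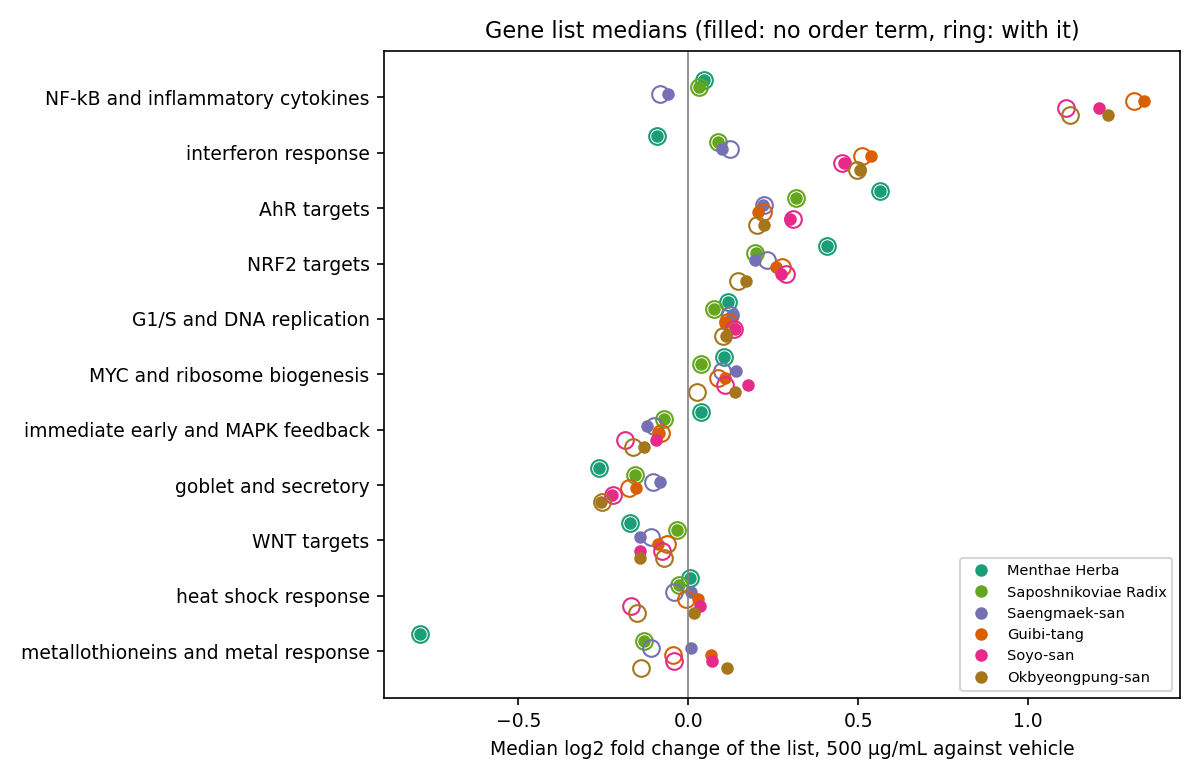
Median log2 change against vehicle (horizontal axis) of 11 gene lists at the high dose of each of the 6 replicated extracts; filled points are without and rings with the order term. NF-kB medians of 1.34, 1.21 and 1.24 for Guibi-tang, Soyo-san and Okbyeongpung-san stand apart from those of the other 3 extracts.

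The high doses were then compared between extracts. Menthae Herba had higher CYP1A1 than Saposhnikoviae Radix by 2.11 ± 0.22 (log2 ± SE, n = 3 and 3), and higher HMOX1 (0.63), ALDH3A1 (0.56), AKR1B10 (0.44) and GPAT3 (0.43). NOX1 (-0.83), MT2A (-0.72), RNF144B (-0.67), MT1E (-0.67) and the GABA receptor subunit GABRP (-0.61) were lower. In all 84 genes were higher and 103 lower (edgeR), with 11 of 26 NRF2 targets (22 adjusted over the list alone) and 5 of 8 AhR targets (5) higher and 3 of 8 metallothionein genes lower (6) and 1 higher. The count was 123, 105 and 123 without Menthae Herba high replicates 1, 2 and 3, and 116 and 109 without Saposhnikoviae Radix high replicates 2 and 3.

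Saengmaek-san and Guibi-tang, whose library names also share a first number, differed in their chemokines. CXCL1 was lower under Saengmaek-san by -4.01 ± 0.15 (log2 ± SE, n = 3 and 3), PI3 by -2.53, CXCL8 by -1.92, ICAM1 by -1.41 and BIRC3 by -1.14. DHRS2 (0.44), the monoamine oxidase MAOA (0.23), the iron oxidase HEPH (0.21), COPG2 (0.20) and the glycosyltransferase GALNT12 (0.19) were higher. In all 7 genes were higher and 56 lower (edgeR). Under Saengmaek-san 15 of 19 NF-kB genes (17 adjusted over the list alone) and 3 of 29 interferon response genes (19) were lower.

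Soyo-san and Okbyeongpung-san, whose library names share their first number, did not differ in any gene at the high dose (edgeR, n = 3 and 3), with 760 genes at an unadjusted p under 0.05 and 2 called by DESeq2. CXCL8 differed by 0.01 ± 0.09 and CYP1A1 by 0.79 ± 0.27 (adjusted p = 1), and no NF-kB or interferon gene passed (1 and 0 adjusted over the list alone). Without Soyo-san high replicate 3 there were 10 calls.

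The formulas were also set against the herb each contains. Soyo-san had higher CXCL1 (3.46; 3.17 with the order term), PI3 (2.31), MX1 (1.45; 1.58), CXCL8 (1.41) and ICAM1 (1.3) than Menthae Herba at the high dose, and lower CYP1A1 (-1.69; -1.90), EGR1 (-0.82), HMOX1 (-0.70; -0.59) and SLC22A3 (-0.58; -0.41). KRT10-AS1 (-0.61) and CDKN1A (-0.34) were lower without the term and not with it (-0.02 and -0.10; adjusted p = 0.972 and 0.791). In all 770 genes were higher and 700 lower, and 172 and 149 with the term (edgeR, n = 3 and 3). Compared with the herb, in the fit without the term, 16 of 19 NF-kB (16 adjusted over the list alone) and 22 of 29 interferon genes (26) were higher, and 12 of 26 NRF2 targets (14) and 5 of 8 AhR targets (7) lower. Of the 1470 genes called in that fit, 237 were kept with the term and 1233 lost, so these list counts may rest in part on the library order. The count was 934 and 533 without Menthae Herba high replicates 1 and 2, and 744 and 805 without Soyo-san high replicates 1 and 2.

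Okbyeongpung-san had higher CXCL1 (3.80; 3.51 with the order term), PI3 (2.45), CXCL8 (1.65), ICAM1 (1.34) and MX1 (1.06) than Saposhnikoviae Radix at the high dose. Its lower genes by the naming rule did not pass with the term. The phosphatase DUSP2 went from -0.50 to -0.24 (edgeR adjusted p = 0.897), C15orf61 from -0.45 to -0.12 and SPRN from -0.44 to -0.16 (adjusted p = 1 for both). EGR1 (-0.49 ± 0.13, then -0.54 ± 0.16; adjusted p = 0.276) and the translational regulator CPEB2 (-0.47 ± 0.12, then -0.55 ± 0.14; adjusted p = 0.0858) kept their differences, with a larger SE. In all 473 genes were higher and 280 lower, and 45 and 9 with the term (n = 3 and 3). Compared with the herb, 17 of 19 NF-kB genes (17 adjusted over the list alone) and 12 of 29 interferon genes (22) were higher, 14 and 4 with the term. The count was 108, 92 and 1136 without Okbyeongpung-san high replicates 1, 2 and 3, and 144, 83 and 267 without Saposhnikoviae Radix high replicates 1, 2 and 3.

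Whether a formula and its herb moved the same genes was measured by the covariance of their fold changes against the shared vehicle over 17049 genes. For Soyo-san and Menthae Herba it was 0.0395, against 0.0263 (SD 0.00151) in 100 simulated sets of unchanged groups sharing the same vehicle libraries, a difference of 0.0133. The correlation across genes, which are not independent replicates, was 0.437, and 0.484 (0.450 to 0.530) in the simulated sets. Both raised 289 genes and both lowered 271, where independent lists would share 62.8 and 43.7. For Okbyeongpung-san and Saposhnikoviae Radix the covariance was 0.0312 against 0.0260 (SD 0.00163), a difference of 0.00525, the correlation 0.387 against 0.475 simulated, and 31 genes rose and 20 fell in both, where independent lists would share 2.18 and 1.06. Part of these overlaps may come from the shared controls, which were not split here, since 1 side would keep a single library. With the order term Soyo-san and Menthae Herba shared 347 rises and 258 falls (42.7 and 28.7 for independent lists), and the other pair 55 and 45 (1.43 and 0.945). The differences in covariance with it were 0.0207 and 0.0156, and without vehicle replicate 1 they were 0.00919 and 0.000697. The simulated sets took their spread from the fit used. Without the order term that spread includes the difference between library parts (common coefficient of variation 0.0524, against 0.0434 with it). Each group simulated lies in 1 part, so the simulated covariances and correlations without the term may be too high. The larger differences with the term may come in part from its smaller simulated spread.

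The readouts fixed beforehand gave few further changes at the high doses. DDIT3, of the unfolded protein response, changed by 0.01 under Menthae Herba, where HMGCS1 (0.09; edgeR adjusted p = 0.141), TXNIP (-0.18; 0.0665), CDKN1A (0.19; 0.247), MYC (-0.06), MKI67 (-0.08) and CXCL8 (0.28; 0.0745) did not pass either. HMOX1 had log2 changes of 0.34 under Saposhnikoviae Radix (adjusted p = 0.111), 0.32 under Saengmaek-san (0.0515, and 0.0216 with the order term) and 0.04 under Okbyeongpung-san. Under Soyo-san the cholesterol synthesis gene HMGCS1 rose by 0.14 (adjusted p = 0.0152) and TXNIP fell by 0.25 (adjusted p = 0.0071). With the term these were 0.14 (adjusted p = 0.0494) and -0.29 (adjusted p = 0.0107). MYC did not pass in any of the 18 comparisons with vehicle without the order term, and with it fell under Saengmaek-san (-0.24, edgeR adjusted p = 0.00168) and Okbyeongpung-san (-0.36, 2.1e-05) at the high dose. The fall under Okbyeongpung-san rests on an order difference taken from Saengmaek-san and Guibi-tang. Markers of immune cells, of which 5 of 15 were measured, were not called as a list under any of the 6 high doses (camera adjusted p from 0.803 to 0.958). Only 2 of 12 fibroblast, 4 of 10 endothelial, 3 of 14 hepatocyte and 2 of 9 lung epithelial markers were measured, too few for the test.

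In GENCODE release 29 on GRCh38, CYP1A1 (ENSG00000140465) lies on chromosome 15 from 74719542 to 74725610 and CYP1B1 on chromosome 2 from 38066973 to 38109902. CXCL8 (chromosome 4, 73740506 to 73743716) and CXCL1 (chromosome 4, 73869393 to 73871242) stand close together, PI3 lies on chromosome 20 (45174876 to 45176544), GCLM on chromosome 1 (93885205 to 93909456), HMOX1 on chromosome 22 (35380361 to 35394214) and MUC2 on chromosome 11 (1074875 to 1110511). Each value sums the annotated transcripts of the gene over exons. Reads of near-identical relatives can be divided between genes in such counts, so single values for AKR1C1, AKR1C2 and AKR1C3, the metallothioneins, CXCL1, CXCL2 and CXCL3, NPIPB12 and UGT1A1 are uncertain, as is that of the antisense gene KRT10-AS1, since the strand setting is not given in the sources used here.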

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

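The tests of the replicate number, of the library batch behind the chemokines and the low-dose changes, of the immune markers other than LYZ, of the single herb and of the library set were chosen only after the result was seen. Direct tests of one extract against another at the high dose, which compare their effects against the shared vehicle, found differences in 187 genes for Menthae Herba and Saposhnikoviae Radix, in 63 for Saengmaek-san and Guibi-tang, in 1470 for Soyo-san and Menthae Herba and in 753 for Okbyeongpung-san and Saposhnikoviae Radix. In the last 2 pairs every library of the formula is of the later part of the numbering and every library of the herb of the earlier part. With the order term these pairs gave 321 and 54 genes, of which 237 and 47 were among the calls without it, and leaving out 1 library gave 83 to 1136 for the second.

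The libraries of Soshiho-tang, which contains Scutellaria, entered no test, having 1 library per dose and so no replicate check. At the high dose its library held CYP1A1 at 160 CPM, against 0.487 ± 0.132 CPM in the 3 vehicle libraries, with 1.69 CPM at the low and 4.30 CPM at the medium dose. CYP1B1 stood at 381 CPM against 44.9 ± 0.330, the retinaldehyde dehydrogenase ALDH1A3 at 119 CPM against 23.6 ± 0.480, and CXCL1 at 19.8 CPM against 2.07 ± 0.233. INO80B-WBP1, a readthrough gene that overlaps its neighbours and is therefore uncertain, was at 6.52 CPM against 0.384 ± 0.115 in vehicle and at 0 in the low-dose library.

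The first pattern weighed is the parting of the libraries on the first principal component by their place in the numbering. Against the replicate number as its source, the libraries numbered replicate 2 of Saengmaek-san and Guibi-tang fell in both parts, 4 in the earlier and 2 in the later. Their gap of 26.2 on the component adds no test, since the parts were cut by the sign of that component. Against GC content, Spearman's rho across genes between the later minus earlier difference and the GC share of the longest transcript was -0.0151, over 16921 genes. The difference estimated from Saengmaek-san correlated across genes with that from Guibi-tang, r = 0.473, but the parting had been seen in both, so this value cannot tell a batch of library making or sequencing from a difference in culture or handling. The step at which the parts diverged stays open, and no biological explanation was tested.

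The second pattern is the higher chemokine and NF-kB genes in Guibi-tang, Soyo-san and Okbyeongpung-san, beside which the single high-dose library of Soshiho-tang had a list median of 0.82 as well. Against the library batch, the list median for Guibi-tang at the high dose was 1.26 in the earlier-numbered libraries alone, where 16 of 18 measured genes rose over vehicle. Summed immune markers rose in Guibi-tang by 39.2% of the rise of the list, a test that decides nothing since LYZ makes up most of that sum and is at 1430 ± 21.7 CPM in vehicle; the other 14 markers summed to 16.7 ± 1.13 CPM in vehicle and 15.5 ± 0.171 CPM in Guibi-tang, and their difference from vehicle was -0.727%, -0.826% and -0.823% of the rise of the list in Guibi-tang, Soyo-san and Okbyeongpung-san, which argues against RNA from immune cells. Against Saposhnikoviae Radix alone as the source within Okbyeongpung-san, 14 list genes were higher in the formula than in the herb with the order term, and the herb's list median was 0.03. Formula and herb also differ in their library number, and the order term cannot remove an offset particular to the formula's set of libraries. What stays open is an effect of components of these extracts or of something else in their preparation such as bacterial endotoxin. For Soyo-san and Okbyeongpung-san the handling of their set of libraries stays open too. These formulas had no earlier libraries, and no vehicle library with their library number was used here. None of these explanations was tested, so a biological reading may be offered only as a hypothesis.

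The third pattern is that Soyo-san and Okbyeongpung-san differed from vehicle in many genes at the low dose (670 and 1498) and in few between high and low dose (22 and 1). On the library batch as the whole source, 842 genes were called for the low dose of Okbyeongpung-san with the order term. Of these, 407 were among the 1498 called without it and 435 were not, while 1091 of the 1498 were lost. The term comes from Saengmaek-san and Guibi-tang alone and cannot remove an offset particular to the other libraries, so this count does not decide. Of the 842, 52.6% were called in the same direction for the low dose of Soyo-san (443 genes), part of which may come from the vehicle and the estimate of the order term that both comparisons share. No vehicle library with the library number of these formulas was used here, so the handling of that set of libraries and the extracts cannot be told apart here.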

How the results depend on the processing

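The order term and the fit of the earlier-numbered libraries were added after the data had been seen, and the other alternatives were fixed beforehand. No gene named by rule turned its direction under an alternative where it passed with or without that alternative. Lists and balances did turn. Cytosolic ribosomal proteins under Okbyeongpung-san at the high dose were called higher (adjusted p = 0.0012) and with the order term lower (adjusted p = 0.0499), neither of which held with an estimated correlation (0.579 and 0.756 as that p). Heat shock genes in the Soshiho-tang high-dose library went from a median of 0.18 to -0.06. Whether more genes rose or fell depended on the setting in several comparisons, as for Soyo-san at the high dose with no filter (1146 up and 1168 down, against 1369 and 1097). DESeq2's size factors in place of TMM left each of the 41 counts of genes or lists within 1.5 times its value. The genes named by rule gave 1034 results, of which 442 passed. Of 5672 alternative values of these, 4835 stayed past the threshold and 837 did not, and 206 of the 442 failed it under at least 1 of the alternatives fixed beforehand. Fewer libraries in a fit give fewer degrees of freedom and fewer genes a different adjustment. Where all libraries compared lie in the same part of the numbering, the order term acts on the estimated spread rather than the fold changes. Beyond that the cause of each difference below was not tested. Counts not given below for a setting stayed within 1.5 times: 24 of 41 with the order term, 8 in the earlier-numbered libraries, 4 of 29 in the fit of the groups compared, 21 of 41 with no filter, 18 of 29 by DESeq2, 35 of 41 with the replicate block and 11 with the block within sets. Depth limits low genes: a gene at 0.488 CPM, as CYP1A1 in vehicle, rests on few counts per library.

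With the order term, the number of genes called was 300 and 124 for Menthae Herba at the medium and low dose, 200, 39 and 115 for Saposhnikoviae Radix at the high, medium and low doses and 297 and 46 for Saengmaek-san at the medium and low dose against vehicle. It was 617 for Guibi-tang at the high dose, 1221 and 506 for Soyo-san at the high and medium dose and 401, 334 and 842 for Okbyeongpung-san at the high, medium and low doses. Between high and low dose it gave 22 for Saengmaek-san and 36 for Soyo-san. The pairs of extracts gave 321 for Soyo-san against Menthae Herba and 54 for Okbyeongpung-san against Saposhnikoviae Radix. The covariance difference there was 0.0207 for Soyo-san and Menthae Herba and 0.0156 for Okbyeongpung-san and Saposhnikoviae Radix. In the earlier-numbered libraries alone the number was 2570, 849 and 546 for Menthae Herba at the high, medium and low doses, 525, 189 and 459 for Saposhnikoviae Radix at the high, medium and low doses and 1537, 505 and 51 for Saengmaek-san at the high, medium and low doses against vehicle. It was 714 for Guibi-tang at the high dose. Between high and low dose it gave 803 for Menthae Herba, 19 for Saposhnikoviae Radix and 22 for Saengmaek-san. Between extracts it gave 406 for Menthae Herba against Saposhnikoviae Radix. No value could be had there for Soyo-san or Okbyeongpung-san, which had no earlier libraries. The same holds for Guibi-tang at the medium and low dose and between high and low dose, since those lower doses had too few earlier libraries.

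In a fit of only the libraries compared it was 2427, 808 and 365 for Menthae Herba at the high, medium and low doses, 745, 353 and 561 for Saposhnikoviae Radix at the high, medium and low doses and 51, 28 and 4 for Saengmaek-san at the high, medium and low doses against vehicle. It was 210, 99 and 48 for Guibi-tang at the high, medium and low doses, 1245 for Soyo-san at the low dose and 369 and 2338 for Okbyeongpung-san at the medium and low dose. Between high and low dose it gave 674 for Menthae Herba, 29 for Saposhnikoviae Radix, 0 for Saengmaek-san, 5 for Guibi-tang and 11 for Soyo-san. Extract against extract gave 644 for Menthae Herba against Saposhnikoviae Radix, 27 for Saengmaek-san against Guibi-tang, 2 for Soyo-san against Okbyeongpung-san, 3081 for Soyo-san against Menthae Herba and 2008 for Okbyeongpung-san against Saposhnikoviae Radix. With no filter on low counts it was 395 and 359 for Menthae Herba at the medium and low dose, 358, 223 and 372 for Saposhnikoviae Radix at the high, medium and low doses and 320 and 172 for Saengmaek-san at the medium and low dose against vehicle. It was 794 and 589 for Guibi-tang at the medium and low dose, 1078 for Soyo-san at the low dose and 1234 for Okbyeongpung-san at the medium dose. High against low dose gave 91 for Saposhnikoviae Radix, 128 for Saengmaek-san, 201 for Guibi-tang, 164 for Soyo-san and 96 for Okbyeongpung-san. The pairs of extracts gave 301 for Menthae Herba against Saposhnikoviae Radix, 165 for Saengmaek-san against Guibi-tang, 95 for Soyo-san against Okbyeongpung-san and 1665 for Okbyeongpung-san against Saposhnikoviae Radix. The covariance difference there was 0.00852 for Soyo-san and Menthae Herba.

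By DESeq2 it was 37 for Menthae Herba at the low dose, 132, 25 and 67 for Saposhnikoviae Radix at the high, medium and low doses and 128 and 33 for Saengmaek-san at the medium and low dose against vehicle. High against low dose gave 11 for Saposhnikoviae Radix, 22 for Saengmaek-san, 36 for Soyo-san and 2 for Okbyeongpung-san. Between extracts it gave 2 for Soyo-san against Okbyeongpung-san. With the replicate number as a block over all groups it was 23 for Menthae Herba at the low dose and 20 and 46 for Saposhnikoviae Radix at the medium and low dose against vehicle. High against low dose gave 8 for Saposhnikoviae Radix and 17 for Saengmaek-san. Extract against extract gave 1163 for Okbyeongpung-san against Saposhnikoviae Radix. With a replicate block within each library set it was 10 for Saposhnikoviae Radix, 24 for Saengmaek-san, 111 for Guibi-tang and 37 for Soyo-san between high and low dose. The blocks moved no other count by over 1.5 times. In the labels the libraries compared share only numbers, and for Saengmaek-san against Guibi-tang at the high dose the correlations may follow the library order. Every library also correlated best with its own number in Saposhnikoviae Radix medium against vehicle, Menthae Herba against Saposhnikoviae Radix and Soyo-san against Okbyeongpung-san, a hint from the data and not from the design. With an estimated correlation the list test called 4 for Saposhnikoviae Radix, 3 for Saengmaek-san, 8 for Guibi-tang, 7 for Soyo-san and 5 for Okbyeongpung-san against vehicle. High against low dose gave 3 for Saposhnikoviae Radix, 1 for Saengmaek-san, 3 for Guibi-tang, 7 for Soyo-san and 2 for Okbyeongpung-san.

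Leaving out 1 library at a time gave 750 to 978, 19 to 68 and 3 to 12 for Menthae Herba at the high, medium and low doses, 17 to 57, 3 to 8 and 5 to 20 for Saposhnikoviae Radix at the high, medium and low doses against vehicle. It gave 95 to 1038, 4 to 64 and 5 to 11 for Saengmaek-san at the high, medium and low doses, 158 to 255, 71 to 604 and 58 to 576 for Guibi-tang at the high, medium and low doses. It gave 1037 to 2375, 653 to 1391 and 182 to 415 for Soyo-san at the high, medium and low doses, 431 to 930, 159 to 933 and 648 to 1118 for Okbyeongpung-san at the high, medium and low doses against vehicle. For high against low dose the count ran from 251 to 295 for Menthae Herba, 1 to 4 for Saposhnikoviae Radix, 0 in each case for Saengmaek-san, 22 to 75 for Guibi-tang, 0 to 80 for Soyo-san and 0 to 1 for Okbyeongpung-san. For pairs of extracts it ran from 105 to 127 for Menthae Herba against Saposhnikoviae Radix, 0 to 10 for Soyo-san against Okbyeongpung-san, 533 to 1058 for Soyo-san against Menthae Herba and 83 to 1136 for Okbyeongpung-san against Saposhnikoviae Radix. The number of lists called against vehicle ran from 7 to 12 for Saposhnikoviae Radix. The number between high and low dose ran from 7 to 11 for Saposhnikoviae Radix and 5 to 11 for Okbyeongpung-san. The covariance difference ran from 0.00919 to 0.017 for Soyo-san and Menthae Herba and 0.000697 to 0.00736 for Okbyeongpung-san and Saposhnikoviae Radix.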

Other observations

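The order difference taken off the Soshiho-tang values was chosen after the results were seen, and EGR1 was not among the readouts fixed beforehand. In the high-dose library of Soshiho-tang, AhR targets had a median log2 change of 1.21 against the vehicle mean, NRF2 targets 0.63 and NF-kB genes 0.82, each above all of 10000 random lists of the same size and expression. CXCL8 was at 24.8 CPM against 7.86 ± 0.194 in vehicle, HMOX1 at 24.5 against 10.4 ± 0.601, and the chemokine CCL20 at 1.64 against 0.143 ± 0.0516. Cholesterol synthesis (0.26) and MYC and ribosome biogenesis (0.29) had medians above all random lists, while those of goblet and secretory genes (-0.48), mitochondrially encoded genes (-0.30) and WNT targets (-0.33) lay at percentiles 0, 0 and 0.01. The mitochondrial share of counts was also high in vehicle, so its cause is open. The mucin MUC2 was at 14.0 CPM against 29.3 ± 1.04. CD200 (0.754 CPM against 5.07 ± 0.128), NOX1 (4.17 against 14.9 ± 0.425), the sulfotransferase CHST3 (4.97 against 14.9 ± 0.988), SLC38A11 (4.39 against 13.0 ± 0.480) and GABRP (4.53 against 13.0 ± 0.854) had the lowest ratios to vehicle among the genes that met the naming rule. Interferon response genes had a median of -0.13 at percentile 18.2, and between the high and low dose -0.56 at percentile 0. These libraries are of the later part of the numbering; with the order difference taken off, the heat shock median went from 0.18 to -0.06 and its percentile from 93.1 to 0.36. Cytosolic ribosomal proteins turned too (0.07 to -0.09, percentile 8.4 to 0). Percentiles went from 35.8 to 0.47 for metallothioneins, from 96.7 to 46.3 for G2/M and from 54.1 to 98.3 for fatty acid synthesis.

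Several lists had medians of the same sign in extracts of different make-up, none of them tested against each other. Goblet and secretory genes had negative medians under all 6 high doses, from -0.26 for Menthae Herba and Okbyeongpung-san to -0.08 for Saengmaek-san, and genes of G1/S and DNA replication positive ones, from 0.08 for Saposhnikoviae Radix to 0.14 for Soyo-san. With an estimated correlation the goblet list did not hold for Saengmaek-san. The G1/S list for Saposhnikoviae Radix was lost when the order term was added besides. Every one of these comparisons uses the same 3 vehicle libraries, the only ones whose sample labels give DMSO. A chance value or other trait of the vehicle would give the same sign in all of them. EGR1 averaged 50.0 ± 1.97 CPM in vehicle and between 25.9 and 47.4 CPM in the 18 treated groups, and MUC2 29.3 CPM in vehicle and between 17.4 and 25.3 CPM in them.

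The 6 libraries of a comparison can be split in 10 ways with the real one, and 10 splits cannot give a share under 0.05. Against vehicle the real split called the most genes in every comparison, 1 split of the 10. It called 1461, 126 and 10 for Menthae Herba at the high, medium and low doses, 85, 5 and 29 for Saposhnikoviae Radix and 730, 71 and 16 for Saengmaek-san. It called 385, 183 and 145 for Guibi-tang, 2466, 1682 and 670 for Soyo-san and 1261, 639 and 1498 for Okbyeongpung-san. The highest of the other splits called 10 for the low and 1 for the medium dose of Guibi-tang, 1 for the high and low doses of Soyo-san, 2 for the medium dose of Okbyeongpung-san and 0 for the others. For Soyo-san and Okbyeongpung-san the real split is also that of the earlier from the later libraries, so the library order alone could put it first. A fit with the order term called 1221, 506 and 665 genes for Soyo-san and 401, 334 and 842 for Okbyeongpung-san at the high, medium and low doses. Between high and low dose the real split called 402 genes for Menthae Herba, 5 for Saposhnikoviae Radix, 4 for Saengmaek-san and 22 for Soyo-san, and the highest other 0, 0, 0 and 6. For Guibi-tang 2 of the 10 splits called at least the real 60 genes. The other, with 648, set its earlier-numbered libraries (high replicates 1 and 2 and low replicate 1) against the later ones. That is many times the real count and points to structure of the samples along the library order. The real comparison with the order term gave 71. For Okbyeongpung-san the real split and 1 other (2 of the 10) called 1 gene each. Between extracts the real split called 187 for Menthae Herba against Saposhnikoviae Radix, 1470 for Soyo-san against Menthae Herba and 753 for Okbyeongpung-san against Saposhnikoviae Radix, and the highest other 0 in each. The last 2 follow the library order as well, and with the order term gave 321 and 54. For Soyo-san against Okbyeongpung-san all 10 splits called at least the real 0, the highest being 2. For Saengmaek-san against Guibi-tang 2 of the 10 splits called at least the real 63, the other calling 116 with Saengmaek-san replicates 1 and 2 and Guibi-tang replicate 2, all of the earlier part, on one side. The real comparison with the order term gave 84.

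The list test with its preset correlation called many lists in other splits too. Each of those splits keeps part of the real difference, so such calls need not be false. Against vehicle the real and the highest other split called 18 and 14 lists for Menthae Herba, 11 and 6 for Saposhnikoviae Radix, 14 and 9 for Saengmaek-san, 17 and 12 for Guibi-tang, 13 and 13 for Soyo-san, where 3 of the 10 splits called as many as the real one, and 14 and 13 for Okbyeongpung-san. Between high and low dose they called 19 and 12 for Menthae Herba, 12 and 6 for Saposhnikoviae Radix, 15 and 10 for Saengmaek-san, 9 and 11 for Guibi-tang (2 of the 10 splits), 14 and 12 for Soyo-san and 8 and 10 for Okbyeongpung-san (4 of the 10).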
